A study of Mus musculus with 9 samples.

How the data were processed

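XBP1 chromatin immunoprecipitation and sequencing (ChIP-seq) was performed by the authors on mouse liver, and the deposited data used here were 8 lists of peaks, 1 per immunoprecipitated library. The series holds 9 samples, and the input DNA of basal liver was not analysed here. Per the labels' protocols, liver was fixed with formaldehyde, chromatin was sonicated and precipitated with the anti-XBP1 antibody M-186, and XBP1 was silenced by tail vein injection of an adenovirus expressing a short hairpin RNA, with clodronate liposomes injected beforehand to lower the viral dose. The protocols also name a control virus, but the labels do not say whether the unsilenced livers received it, nor whether a library came from 1 animal or a pool. Per the submitters' processing notes, the tools were Bowtie2 and MACS 1.4.2 and the genome build was mm9; their settings, and whether the input served as control in peak calling, are not given in the sources used here. Groups were taken from the sample titles.

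Each list gave chromosome, start, end, a peak name and a score. The score deposited by the authors was taken as −log10 of a p-value, from the values themselves. In each list, between 26.6% and 61.8% of the scores fell on the steps that −log10 of Poisson tail probabilities takes for a single background mean. The best match on a scale 10 times as fine (10 times −log10 of p) reached from 7.36% to 35.3%. The step pattern was weakest for the silenced basal list, at 26.6% against 21.5% for the next best mean. The design had assumed that scale, with a strict threshold of 100, and this was replaced by a score of 10, the same p-value. Scores are the authors' own values per peak and were used to describe, rank or filter peaks within a list, except in 1 matching of peaks by score between both 6 h lists, given with its replacement by rank. The background mean read from the steps, divided by the width of the shortest peak, was compared between lists. Relative to the library 6 h after hepatectomy it lay within 1% of 1 in 5 other lists, at 0.898 in basal liver and at 0.637 in silenced basal liver. A value shared by most lists can be set by scaling or subsampling in the calling, so it does not give the sequencing depth.

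Coordinates are in mm9, written 1-based. The gene table at hand was made on GRCm38, and 604 peaks on 9 chromosomes lay beyond its last gene, so no position was converted between builds and peaks are named by coordinates alone. For that reason the planned counts of peaks near genes of fixed lists, cell type markers included, and the planned motif count were not run.

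Peaks of a pair of libraries were called shared where they overlapped by at least 1 bp. The share of peaks overlapped was computed in both directions with Clopper-Pearson 95% intervals. Chance overlap was estimated with 1000 circular shifts of the peaks compared along each chromosome. Shares were also computed by decile of score and for the 1000 highest-scoring peaks. The 5 unsilenced lists were merged into regions and each region was marked by the lists with a peak in it. Overlaps and intervals were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plotted with matplotlib 3.10.9. On lists simulated with a known overlap the counts were checked with bedtools 2.31.1. There the computed share differed from the true one by at most 0.05 percentage points. The simulated counterparts kept the width of their peaks and were moved by less than it. This checks the counting only and does not cover lists of unlike widths. No test within a state was possible with 1 library per condition, and no p-value was computed across sites. Peak numbers with and without silencing were compared over the 3 states as pairs with an exact sign-flip permutation test (two-sided) of the log2 ratio, chosen after seeing the data.

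The comparisons, the alternatives and the rule for named sites were set before the data were examined. The rule took, per comparison, the 5 highest-scoring peaks of the hepatectomy or unsilenced library that overlapped no peak of the other library and the 5 highest-scoring that did. The same form was used for the sham time course. Alternatives were midpoints within 250 bp, overlap of at least 50% of both peaks, a score of at least 10 in both lists, equal numbers of highest-scoring peaks, and peaks of 2 kb or less on chromosomes 1 to 19 and X. For peak numbers, merging of peaks within 500 bp was also tried. Chosen after seeing the data were the silenced 6 h library in place of the other silenced libraries, peaks resized to 500 bp, time courses without the basal library, and a score of at least 20 for the ratio of hepatectomy to sham peaks.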

Results

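XBP1, a transcription factor of the unfolded protein response that is switched on by IRE1-dependent splicing of its messenger RNA, was mapped on chromatin of livers of C57Bl6-J mice by immunoprecipitation with an antibody to XBP1 and sequencing. Partial hepatectomy, the removal of most of the liver, sets off regeneration of the remaining lobes, and the series asks which sites XBP1 occupies while this takes place. The deposited lists held the regions (peaks) called in 8 libraries, with 1 library per condition. They came from basal liver, liver 6 h and 48 h after partial hepatectomy, liver 6 h and 48 h after a sham operation, and 3 livers in which XBP1 had been silenced with an adenovirus carrying a short hairpin RNA (shXBP1) 7 days earlier. The silenced livers were basal, 6 h after hepatectomy and 48 h after hepatectomy. With 1 library per condition no difference could be set against a spread between animals, so values below describe these libraries, and 95% Clopper-Pearson intervals of shares cover counting error only. Read numbers per library were not given in the sources used here.

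The number of XBP1 peaks differed widely between the states of the liver. The basal library had 2482 peaks, which covered 0.89 Mb. The library taken 6 h after hepatectomy had 22071 peaks over 10.993 Mb, and the sham library of the same time had 23087 peaks over 10.879 Mb. At 48 h the number was 7212 after hepatectomy and 4622 after the sham operation. The silenced libraries were far shorter, with 177 peaks in basal liver, 4325 peaks 6 h after hepatectomy and 102 peaks 48 h after it. With the 3 states taken as pairs, the log2 ratio of unsilenced to silenced peak numbers was 4.10 ± 1.91 (SD, n = 3), with p = 0.25 in an exact two-sided sign-flip permutation test, the smallest p that 3 pairs allow. The median peak width lay between 290 bp and 429 bp in the unsilenced libraries. It was 333 bp in the silenced 6 h library, and 103 bp and 94 bp in the silenced basal and silenced 48 h libraries, where 49.2% and 53.9% of the peaks were 100 bp wide or less. No peak of the other 6 libraries was that narrow. With a score of at least 10 required, 99 peaks stayed in the silenced basal library and 49 in the silenced 48 h library.

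**Figure D1:**
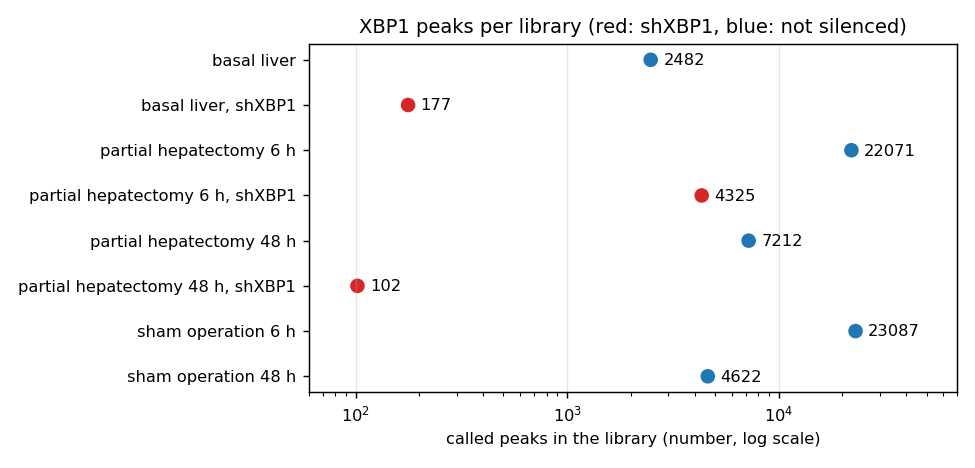
Number of called XBP1 peaks in each of the 8 libraries, on a logarithmic axis, 1 point per library. Each shXBP1 library (red) lies below the unsilenced library (blue) of its state, and both unsilenced 6 h libraries lie highest, at 22071 and 23087.

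Some regions carried a peak in all conditions. In silenced livers, XBP1 left after silencing cannot be told apart from other signal, and the input DNA was not analysed here. Of the 28099 regions obtained by merging the 5 unsilenced lists, 1859 (6.62%) carried a peak in all 5, and 53 carried a peak in all 8 lists, silenced livers included. These 53 sites were spread over 20 chromosomes, and 50 of them were among the 250 highest-scoring peaks 6 h after hepatectomy. The site with the highest score of that library lay on chromosome 10 (86166969 to 86169353, mm9, score 828.25), followed by sites on chromosome 2 (143990559 to 143992082, score 780.16) and chromosome 2 (34626722 to 34628400, score 768.2). The next were on chromosome 3 (95754314 to 95755491, score 744.37) and chromosome 19 (60866155 to 60867412, score 739.62). All 5 had a peak in each of the 8 lists.

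The silenced livers serve as a control for the antibody signal, each compared with the unsilenced liver of the same state. In basal liver 14.0 times fewer peaks were called after silencing, and 118 of the 2482 basal peaks (4.75%, 3.95 to 5.67%) overlapped a peak of the silenced library. The reverse share was 89.3%, so nearly all regions left after silencing were sites of the unsilenced liver. The shortest peak had 53 bp in the silenced basal list and 227 bp in the unsilenced one. A shorter fragment length in the calling thus cannot be told apart from silencing. The highest-scoring basal peak, on chromosome 2 (34627094 to 34628027, score 542.08), had a counterpart, as did those on chromosome 10 (86167963 to 86168948, score 502.54), chromosome 11 (50138837 to 50139818, score 355.17), chromosome 3 (95754490 to 95755193, score 333.27) and chromosome 3 (65196153 to 65196904, score 313.76). The highest-scoring peak without one lay on chromosome 5 (100844890 to 100845887, score 163.72), at rank 39 of the list. It was followed by peaks on chromosome 14 (73002426 to 73003118, score 144.58), chromosome 9 (121627891 to 121628451, score 144.58), chromosome 11 (96777421 to 96778090, score 138.93) and chromosome 7 (148725499 to 148726013, score 135.18). Each of these 5 had a peak in the silenced 6 h library. Among basal peaks in the highest decile by score, 39.9% kept a counterpart, against 0.80% in the lowest decile. The share depended on list length and on the silenced library: it was 54.8% between the 177 highest-scoring basal peaks and the silenced peaks, 71.1% against the silenced 6 h library, and 1.13% where an overlap of at least 50% of both peaks was required. Unlike widths, with medians of 103 bp silenced and 319 bp unsilenced, lower the last share by construction.

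At 6 h after hepatectomy the silenced library held more peaks than the silenced libraries of the other states, a difference that was not tested. The peak number was 5.10 times lower after silencing, and 4174 of the 22071 unsilenced peaks (18.9%, 18.4 to 19.4%) kept a counterpart, against at most 0.249% with the peaks placed at random. Of the silenced peaks, 98.2% (97.8 to 98.6%) lay on a peak of the unsilenced library. The 5 highest-scoring peaks, given above, were all among those kept. The highest-scoring peaks without a counterpart lay on chromosome 4 (95634068 to 95634700, score 246.51, rank 328), chromosome 6 (108778099 to 108778821, score 213.1), chromosome 6 (118428863 to 118429775, score 213.07), chromosome 5 (74812054 to 74812845, score 190.78) and chromosome 4 (122638132 to 122638939, score 188.82). All 5 also had a peak 48 h after hepatectomy and 6 h after the sham operation, and the site on chromosome 6 at 108778099 had a peak in the silenced basal library. The kept share rose with score, from 0.77% in the lowest decile to 87.7% in the highest. Sites found in all unsilenced lists were kept more often: 1534 of the 1859 regions in all 5 unsilenced lists had a silenced 6 h peak, against 124 of the 4835 regions in the unsilenced 6 h hepatectomy list alone. Both groups of regions were not matched for score, so this contrast cannot be told apart from the rise with score. Between equal numbers of highest-scoring peaks the share was 68.0%, and with an overlap of at least 50% of both peaks it was 11.8%.

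At 48 h after hepatectomy few peaks were called in the silenced library. The number was 70.7 times lower than in the unsilenced library, and 66 of the 7212 unsilenced peaks (0.915%, 0.708 to 1.16%) had a counterpart. The shortest peak had 53 bp in the silenced list and 190 bp in the unsilenced one. A shorter fragment length in the calling therefore cannot be told apart from silencing here. Of the 102 silenced peaks, 76.5% (67.0 to 84.3%) lay on an unsilenced one. The highest-scoring peaks of the 48 h library, on chromosome 11 (120433967 to 120435226, score 225.5), chromosome 2 (143990842 to 143992356, score 221.38), chromosome 9 (106793843 to 106794891, score 217.26), chromosome 13 (55463924 to 55464626, score 215.21) and chromosome 2 (34626866 to 34628107, score 211.11), had a counterpart. The highest-scoring peaks without a counterpart lay on chromosome 3 (65195507 to 65196981, score 204.99, rank 7), chromosome 8 (3467444 to 3468118, score 196.88), chromosome 10 (62620946 to 62621651, score 176.85), chromosome 9 (121627831 to 121628447, score 172.89) and chromosome 11 (120432233 to 120432860, score 161.1). All 5 had a peak in the silenced 6 h library, and 4 of them, all but that on chromosome 9, had one in the silenced basal library. Between the 102 highest-scoring peaks and the silenced peaks the share was 51.0%, and against the silenced 6 h library it was 42.6%. In the highest decile by score 8.32% of the peaks kept a counterpart. No pair overlapped by at least 50% of both peaks. Unlike widths, with medians of 94 bp silenced and 290 bp unsilenced, lower this share by construction, so it says little about silencing.

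**Figure D2:**
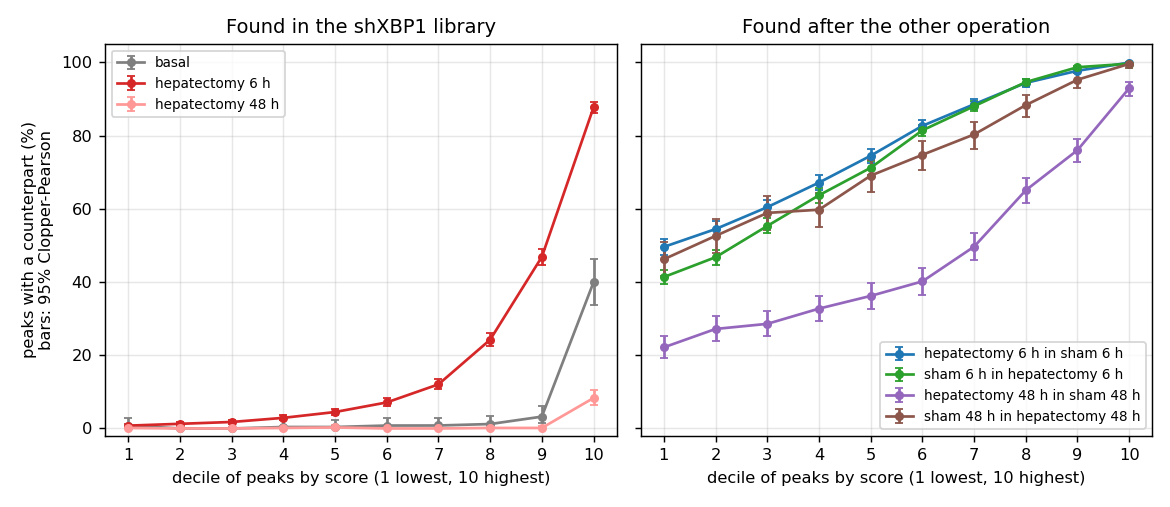
Share of peaks with a counterpart in the compared library (percent, with 95% Clopper-Pearson bars), by decile of the peaks, ranked by score within their own list, for silencing (left) and for the other operation at the same time (right). After hepatectomy at 6 h the share kept under silencing rises from 0.77% to 87.7%, and hepatectomy peaks at 6 h are found after the sham operation in 49.6% of the lowest and 99.9% of the highest decile.

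The sham operation separates removal of liver tissue from the surgery itself. At 6 h both operations gave similar sets of XBP1 sites: 16979 of the 22071 hepatectomy peaks (76.9%, 76.4 to 77.5%) overlapped a sham peak, and 74.1% (73.5 to 74.6%) of the sham peaks overlapped a hepatectomy peak. With the peaks placed at random at most 1.16% of the hepatectomy peaks overlapped a sham peak. The 5 highest-scoring hepatectomy peaks all had a sham counterpart. The first peak without one was at rank 1426, on chromosome 16 (93615198 to 93615779, score 96.35), 10556 bp from the nearest sham peak. The others lay on chromosome 9 (65048392 to 65048851, score 91.26), with a sham peak 353 bp away, chromosome 10 (92540972 to 92541443, score 70.28), chromosome 9 (45924887 to 45925490, score 67.95) and chromosome 9 (35075067 to 35075592, score 67.14). Of these 5 sites, 4 also had a peak in the silenced library 6 h after hepatectomy, and 1 of them, that on chromosome 16, had a peak 48 h after hepatectomy. The ratio of hepatectomy to sham peak numbers was 0.956 over all peaks. It was 1.01 and 1.23 where a score of at least 10 or 20 was required in both lists, whose scores need not share a scale.

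At 48 h the hepatectomy library held more sites than the sham library. Of the 7212 hepatectomy peaks, 3394 (47.1%, 45.9 to 48.2%) overlapped a sham peak, while 72.5% (71.1 to 73.7%) of the 4622 sham peaks overlapped a hepatectomy peak. Between the 4622 highest-scoring peaks of each list the shares were 57.9% and 57.8%. The highest-scoring hepatectomy peaks without a sham counterpart lay on chromosome 12 (77374955 to 77375690, score 86.34, rank 141), chromosome 2 (119912990 to 119913477, score 84.53), chromosome 6 (29609791 to 29610289, score 73.06), chromosome 8 (24318905 to 24319575, score 56.58) and chromosome 5 (31121099 to 31121659, score 54.53). All 5 had a peak in both unsilenced 6 h libraries, that of the sham operation included. All but that on chromosome 2 also had a peak in basal liver. The peak number was 1.56 times that of the sham library. With a score of at least 20 required in both lists the ratio was 0.961, but their scores need not share a scale. Peaks of the hepatectomy library were narrower, with a median of 290 bp against 379 bp and a shortest peak of 190 bp against 266 bp.

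**Figure D3:**
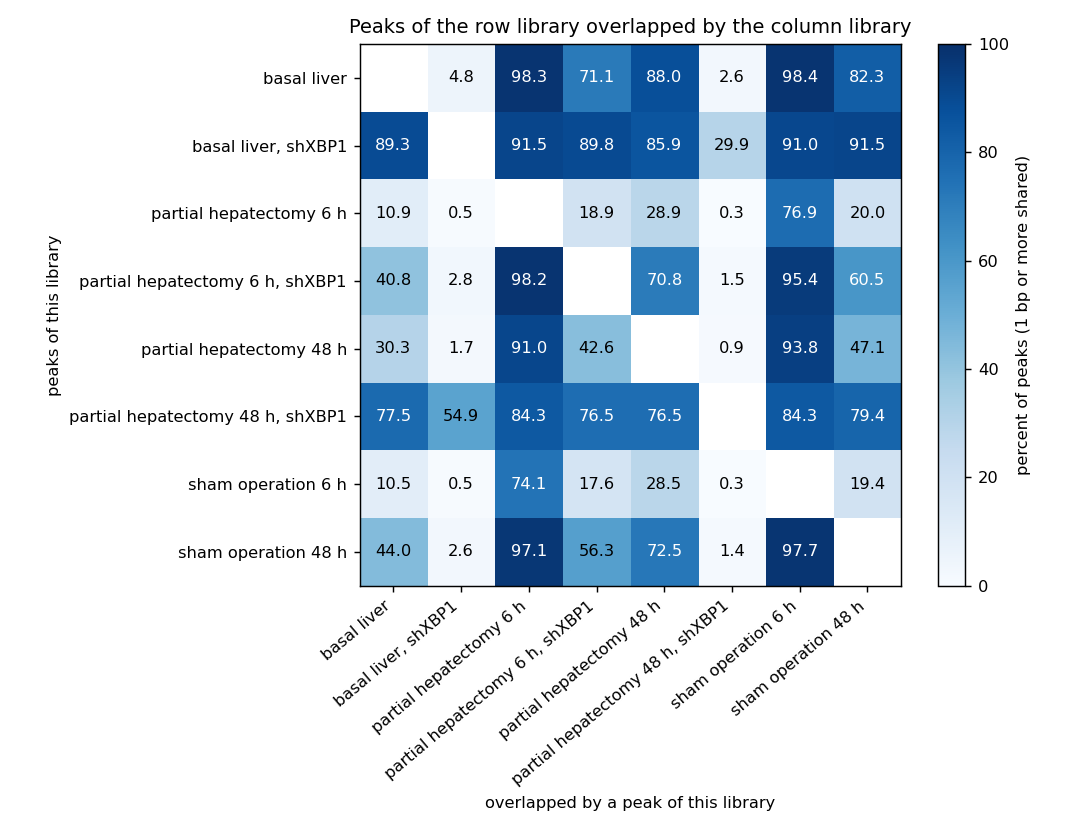
Percent of the peaks of each library (vertical axis) that share at least 1 bp with a peak of each other library (horizontal axis), with darker cells for higher shares. Peaks of basal liver are found in both 6 h unsilenced libraries at 98.3% and 98.4%, whereas 10.9% of the 6 h hepatectomy peaks are found in basal liver.

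In the time course after hepatectomy the called peaks went from the basal list to a much wider set at 6 h and a narrower one at 48 h. The 6 h library had 8.89 times as many peaks as the basal library and the 48 h library 2.91 times as many. Of the basal peaks, 98.3% were found at 6 h and 88.0% at 48 h, and 91.0% (90.4 to 91.7%) of the 48 h peaks were found at 6 h. In the other direction, 10.9% of the 6 h peaks were found in basal liver and 28.9% at 48 h. The share found in basal liver rose from 0.82% in the lowest decile by score to 63.8% in the highest. Since read numbers were not given, a shallower basal or 48 h library cannot be told apart from fewer sites. The highest-scoring 6 h peak absent from the basal list lay on chromosome 11 (118304300 to 118305080, score 413.49, rank 101). The next were on chromosome 16 (5532555 to 5533439, score 332.42), chromosome 13 (64254218 to 64254968, score 315.73), chromosome 2 (32243052 to 32245172, score 285.79) and chromosome 18 (85119718 to 85121452, score 268.18). All 5 also had a peak 6 h after the sham operation, in the silenced 6 h library and 48 h after hepatectomy, and the site on chromosome 13 had a peak in the silenced basal library. Among 48 h peaks absent at 6 h, the highest-scoring lay on chromosome 8 (19979891 to 19980267, score 37.13, rank 539), chromosome 9 (7971915 to 7972246, score 36.56), chromosome 13 (55431288 to 55431898, score 30.32), chromosome 1 (78598715 to 78599099, score 27.99) and chromosome 17 (56791255 to 56791717, score 26.62). Those on chromosomes 9 and 17 had a peak 6 h after the sham operation. The share of basal peaks found at 6 h was 61.1% between equal numbers of highest-scoring peaks and 45.4% where at least 50% of both peaks had to overlap.

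The sham time course had the same order of peak numbers, with 9.30 times the basal number at 6 h and 1.86 times at 48 h. Unknown depth limits this course in the same way. Basal peaks were found at 98.4% in the 6 h and 82.3% in the 48 h sham library, and 97.7% of the 48 h sham peaks were found at 6 h. Of the same 48 h sham peaks, 97.1% were also found 6 h after hepatectomy. The highest-scoring 6 h sham peaks absent from the basal list lay on chromosome 1 (82812420 to 82813078, score 157.84), chromosome 15 (85607277 to 85608148, score 141.62), chromosome 12 (45973528 to 45974196, score 138.0), chromosome 12 (83571466 to 83572029, score 137.29) and chromosome 4 (98234052 to 98234702, score 133.85). All 5 had a peak 6 h after hepatectomy too. Sham peaks at 48 h without a 6 h sham counterpart had low scores, the highest being 19.48 on chromosome 3 (5860694 to 5860974), at rank 1526. Across both courses, 9422 regions (33.5% of the merged regions) had a peak in both 6 h libraries and in no other unsilenced library, and 1 region was found in both 48 h libraries and in neither 6 h library. The share of basal peaks found 6 h after the sham operation was 60.1% between equal numbers of highest-scoring peaks and 52.2% where at least 50% of both peaks had to overlap.

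The window of 100 kb with the most peaks 6 h after hepatectomy, singled out after its values were seen, lay on chromosome 3 between 82800001 and 82900000. It held 35 peaks 6 h after hepatectomy and 23 peaks 6 h after the sham operation, and none in basal liver. At 48 h it held 4 peaks after hepatectomy and 3 after the sham operation, and 3 peaks were called there in the silenced 6 h library.

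**Figure D4:**
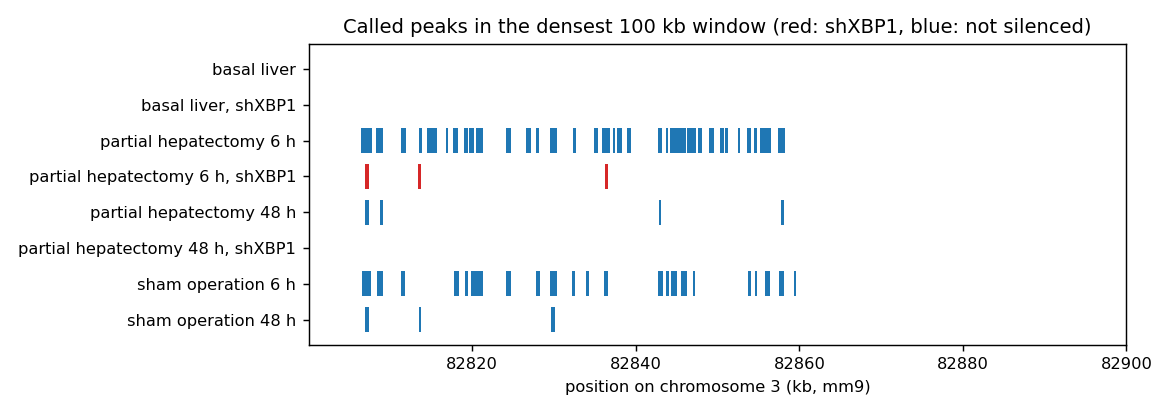
Called peaks of the 8 libraries (shXBP1 in red, unsilenced in blue) along the 100 kb window of chromosome 3 (position in kb, mm9) with the most peaks 6 h after hepatectomy. The 6 h libraries hold 35 and 23 peaks there, the 48 h libraries 4 and 3, and basal liver none.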

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

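The comparison of background means and the ratio at a score of at least 20 were chosen only after the peak numbers had been seen. After hepatectomy the number of XBP1 peaks was 0.956 times that of the sham operation at 6 h and 1.56 times at 48 h. These ratios were singled out because they lie on opposite sides of 1, with 1 library per condition. The difference between the times was not tested. With a score of at least 20 required in both lists the ratio was 1.23 at 6 h and 0.961 at 48 h. Scores of different lists need not share a scale. The highest score was 828.25 after hepatectomy and 331.58 after sham at 6 h, and 225.5 and 773.19 at 48 h. A common score cut therefore does not decide the direction of either ratio.

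The sham operation at 6 h gave as many XBP1 sites as the removal of liver tissue, 9.30 times the basal number. As the source of most of this number, weak calls without a counterpart are argued against: 74.1% of the sham peaks lay on a hepatectomy peak. Random placement gave at most 1.06%, but it moved peaks along whole chromosomes, so other signal common to both lists is not excluded. The 5989 sham peaks without a counterpart had a median score of 10.94, against 16.32 for the whole list. Weak calls may thus make up part of the number. A deeper 6 h library as the reason for the lower number of 4622 sham peaks at 48 h stays open: the ratio of background means per base (sham 48 h over sham 6 h) was 1.0, but 6 of the 8 lists shared this mean to within 0.061%, so it does not measure sequencing depth. Efficiency of the precipitation stays open too, as does a shallower basal library for the rise over the basal number. A candidate explanation, as a hypothesis, is that surgery itself, which both operations share, may bring XBP1 to these sites within 6 h; no liver with anaesthesia and fasting alone was analysed here.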

How the results depend on the processing

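The silenced 6 h library used in place of the others, time courses without the basal library and the score of at least 20 were chosen only after the results were seen. Values depend on how peaks are matched and how many are compared, and with 1 library per condition no replicate could be left out. Requiring at least 50% of both peaks gave kept shares under silencing of 1.13% in basal liver, 11.8% at 6 h and 0.0% at 48 h (0 of 7212 peaks, with an upper Clopper-Pearson bound of 0.05%, or 0.0416% taken as 3 counts), hepatectomy peaks found after sham of 70.4% and 41.7%, and basal peaks found at 6 h of 45.4% after hepatectomy and 52.2% after sham. This setting lowers shares by construction, since widths differ between lists. Midpoints within 250 bp gave 17.8% for silencing at 6 h, 74.1% for hepatectomy peaks found after sham at 6 h, and 90.7% and 92.1% for basal peaks found at 6 h after hepatectomy and sham. A score of at least 10 gave 3.81%, 17.4% and 0.66% for silencing, and 74.6% and 49.8% for hepatectomy peaks found after sham; it left 99 peaks in the silenced basal and 49 in the silenced 48 h list. Equal numbers of highest-scoring peaks gave 54.8%, 68.0% and 51.0% for silencing, 75.3% and 57.9% for hepatectomy against sham, and 61.1% and 60.1% for basal peaks found at 6 h; equal list lengths are the change. Peaks of 2 kb or less on chromosomes 1 to 19 and X gave 97.5% for the hepatectomy course. The silenced 6 h library gave 71.1% in basal liver and 42.6% at 48 h. Without the basal library the courses are described by 48 h peaks found at 6 h, 91.0% after hepatectomy and 97.7% after sham, which is another quantity. The ratio of hepatectomy to sham peaks turned at 6 h to 1.01 (score of at least 10) and 1.23 (at least 20). At 48 h it turned to 0.961 (at least 20). Scores of the compared lists need not share a scale, and the cause was not tested. Another 42 values of the comparisons under these settings stayed within their interval or within 1.5 times the count or ratio. Gene list and motif alternatives were not run. Depth sets how many weak peaks can be called, and read numbers are not given in the sources used here.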

Other observations

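Tests of background means, fragment lengths and recurrence given here were chosen only after the results they bear on had been seen; the tests of the score dependence at 6 h and of the 48 h peaks were set before. Without regard to gene density, copy number of X or the input DNA, XBP1 peaks were thinly spread on the X chromosome for its length. It held 255 of the 22071 peaks 6 h after hepatectomy (1.16%, 1.02 to 1.31%), against 6.32% of the length of chromosomes 1 to 19 and X up to the last peak, and autosomes had 5.77 times the peak density of X. The factor was 7.11 after sham at 6 h, 8.75 in basal liver, 8.47 and 8.84 at 48 h after hepatectomy and sham, and 11.6 in the silenced 6 h library. It was 5.92 in the silenced basal list, with 2 peaks on X, and 2.23 in the silenced 48 h list, with 3 peaks on X (2.94%, 0.611 to 8.36%), an interval that includes the share of the length. Among autosomes chromosome 19 was the densest and chromosome 14 the sparsest in each of the 5 unsilenced lists, with 13.6 and 6.31 peaks per Mb 6 h after hepatectomy.

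Clusters of XBP1 peaks at 6 h, picked by peak number, lay in several other windows of 100 kb. On chromosome 9 (46000001 to 46100000) there were 17 peaks after hepatectomy and 22 after sham at 6 h, and none in basal liver. On chromosome 8 (87500001 to 87600000) there were 19 and 13 peaks, with 2 in basal liver. On chromosome 19 (5800001 to 5900000) and chromosome 2 (167600001 to 167700000) there were 18 peaks each after hepatectomy, with 16 and 19 after sham and 2 and 1 in basal liver. On chromosome 15 (58800001 to 58900000) there were 17 and 16 peaks, with 5 in basal liver. At 48 h after hepatectomy these windows, in the order given, held 7, 5, 6, 6 and 6 peaks.

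Fewer peaks were called in silenced than in unsilenced liver in all 3 states, and a shallower library cannot be told apart from silencing in any of them. The ratio of background means per base, silenced over unsilenced, was 1.0 at 6 h and at 48 h, where it does not measure sequencing depth because 6 of the 8 lists shared this mean to within 0.061%, and 0.709 in basal liver, where the silenced list matched its steps weakly (26.6% of scores against 21.5% for the next best mean). A shorter fragment length in the calling is argued against at 6 h, where the shortest silenced peak had 95.4% of the width of the shortest unsilenced one; it cannot be told apart from silencing in basal liver and at 48 h, where the higher of both values was 27.9%. A partial loss of the same sites at 6 h was not decided by the share with a counterpart, 113.9 times as high in the highest as in the lowest decile by score. Unsilenced lists also gave steep rises, over a wide range. For 6 h peaks found in the basal list they were 77.8 times after hepatectomy and 173.8 times after sham. For 6 h peaks found at 48 h after the same operation they were 16.8 and 62.7 times. Only the sham value in basal liver lay above 113.9. Efficiency of the precipitation, the virus and the liposomes, whose use in unsilenced livers the labels do not state, stay open with the silencing itself.

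Most sites found 6 h after hepatectomy and not after sham did not recur in the silenced 6 h hepatectomy library. That shorter list kept 18.9% of all 6 h hepatectomy peaks. The sites without a sham counterpart had a median score of 12.19, and the decile around that score kept 1.77%, so a low share there is no failed replication. They recurred more often than sham sites without a hepatectomy counterpart. Of 5092 such peaks 143 (2.81%, 2.37 to 3.30%) had a peak in the silenced 6 h hepatectomy library, against 28 of the 5989 sham peaks (0.468%, 0.311 to 0.675%), a ratio of 6.01 (4.01 to 8.99, counting error only). Of the silenced 6 h peaks, 98.2% lay on the 6 h hepatectomy list and 95.4% on the 6 h sham list. The ratio largely describes this closer match and is no separate support for it. Higher ranks of the hepatectomy peaks are argued against as the whole reason, since the ratio was 3.94 (2.59 to 6.01) in common score bins, tried first, and 5.73 (3.82 to 8.60) in deciles of rank within each peak's own list, which replaced them after that value was seen because scores of different lists need not share a scale. The preference ran the other way at 48 h after hepatectomy, where 3.5% of the hepatectomy sites and 6.2% of the sham sites recurred. The ratio of recurring shares was 0.563 (0.473 to 0.670), against 0.795 (0.590 to 1.07) for 48 h after sham and 0.863 (0.498 to 1.49) for basal liver. In deciles of rank these ratios were 0.541 (0.455 to 0.642), 0.748 (0.558 to 1.003) and 0.852 (0.495 to 1.465). In common score bins they were 0.443 (0.372 to 0.527), 0.605 (0.454 to 0.805) and 0.659 (0.395 to 1.099). As a hypothesis, a small set of sites may be particular to the first hours after removal of tissue, but stronger signal at equal rank and shared handling of both hepatectomy libraries of that time stay open. Since the recurrence was read in a library with XBP1 silenced, signal that does not come from XBP1 stays open too.

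The sites occupied 48 h after hepatectomy may be a subset of those occupied at 6 h: 91.0% of the 48 h peaks overlapped a 6 h hepatectomy peak. This share depended on the 6 h list, which held 3.06 times as many peaks. It was 63.7% between equal numbers of highest-scoring peaks and 50.5% where at least 50% of both peaks had to overlap. The subset was not particular to hepatectomy, because 93.8% of the 48 h hepatectomy peaks overlapped a 6 h sham peak. Of the merged regions, 337 were shared by the 48 h hepatectomy and 6 h sham libraries without the other operated unsilenced libraries, against 167 shared by both hepatectomy libraries without a sham library, 69 by both sham libraries without a hepatectomy library, and 60 by the 6 h hepatectomy and 48 h sham libraries without the others. Between the 1000 highest-scoring peaks of each list, 48 h hepatectomy peaks were found at 68.8% in the 6 h sham and 64.1% in the 6 h hepatectomy library, and 48 h sham peaks at 71.9% in the 6 h hepatectomy and 64.8% in the 6 h sham library.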
